A study of Mus musculus with 44 samples.

How the data were processed

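Chromatin accessibility was measured by ATAC-seq and gene expression by RNA-seq in mouse spleen CD8+ T cells. Per the labels' protocols, each ATAC-seq reaction used 50000 cells, except that 10000 were used for 1 memory replicate (which one is not stated) and for the day 35 KLRG1 cells, and libraries were sequenced in pairs. The 44 samples fell into the groups named by their titles: 15 ATAC-seq groups with 1 to 5 libraries and 4 RNA-seq groups with 2 libraries each. One naive and one effector replicate were each sequenced as a pair of technical replicates, and the exhausted ATAC-seq libraries carried replicate numbers 1, 3 and 4. The naive cells of the ATAC-seq were labelled as uninfected, whereas the naive cells of the RNA-seq carried the Arm5 infection label. The labels do not name the agent whose dose in units (10U, 100U) distinguishes the cultures, and the first of these is called resting in the file header. PMA, Iono and CsA were read as phorbol ester, ionomycin and cyclosporin A, and CARIT and DBDmut as names of an engineered NFAT and its DNA-binding mutant. These readings come from background knowledge of the field.

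The ATAC-seq values are a signal deposited by the authors as 1 mean per group, per the file headers, for regions of mm9. From the values, the signal is a read count scaled between libraries and divided by the region's width in kb, rounded to 1 decimal, and every region reached at least 25 in 1 or more of the 15 columns. The submitters' processing notes name mm9, Trim Galore, Bowtie 1.0, MACS2 and DESeq2 with no role or order. How reads were aligned and shifted, how regions were called and how library values were averaged is not given in the sources used here. The RNA-seq values are mean TPM deposited by the authors per group, per the file headers, rounded to 1 decimal, with each of the 4 columns summing to just under the TPM total. The aligner, annotation and strand setting of the RNA-seq are not given in the sources used here, so genes that overlap or have near-identical copies cannot be told from each other in these values. Region starts were written 1-based. No genome or annotation of mm9 was used here, so regions were not assigned to genes, motifs were not searched, and accessibility was not joined to expression gene by gene. Of the 14492 gene symbols, 12977 matched a current table of mouse gene names, and genes were placed on chromosomes through RefSeq records of GRCm38.p6, of which no coordinate was used.

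The comparisons, gene lists, naming rules and most alternatives were fixed from the labels before the data were examined. The planned tests on library values (limma, with edgeR or DESeq2 on recovered reads as alternatives, and camera for lists) could not be made because both tables hold group means, so means were described by size instead, a rule chosen once the tables were seen to hold means. Signal was put on the log2(signal + 1) scale, and a region was counted as higher or lower where the difference was at least 1 on that scale (2-fold) and the higher mean was at least 25. The planned filter (a mean of at least 10 in some group) removed no region. TPM was put on the log2(TPM + 1) scale, with a difference of at least 1 and at least 10 TPM in the higher group. Differences on these scales understate the change of low values. Regions named in the text come from the 3 largest rises and 3 largest falls per comparison among regions reaching 50 in the higher group. The planned condition that replicates must not overlap could not be applied. Genes named in the text are the members of the fixed lists with the largest differences, the 10 largest rises and falls over all genes, and 11 genes fixed for all groups, of which 1 is not reported here, while further members of the lists (such as Batf, Egr1, Btla and Cd3e) and examples of genes listed at 0 were chosen after their values were seen.

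In the cultured columns and the day 35 KLRG1 column, low values lie on steps given by 1 read of 1 library. Steps were fitted for each library, and 99.01% to 100% of values tested came out as whole reads within the rounding to 1 decimal and a small added tolerance. In the day 35 KLRG1 column all values under 15 reads were tested. In each cultured column only 2316 to 3025 low values above 0 in narrow regions were tested, as sums of whole reads of both libraries. These steps gave the reads in regions per library, Poisson intervals (95%) for named regions, and 20 redraws of each comparison under counting error alone. The in vivo columns with several libraries gave no such steps, so their depth is unknown, and reads are not independent molecules without molecular identifiers. The size rule was tested on simulated data: NFAT CARIT and Mock were redrawn over 70532 regions with 200 changed by a known fold, of which 44.5% were recovered at 2-fold, 98.0% at 3-fold and 100% at 4-fold, with 0 in the wrong direction and 138 to 164 unchanged regions counted per direction.

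Shares of a region set that passed in another comparison were given with exact (Clopper-Pearson) binomial intervals and set against 10000 random sets matched on mean level in 20 bins. Overlaps of 2 lists against naive cells were set against independent lists and against 20 simulations of unchanged groups sharing the naive values, with the spread between the effector and SLEC columns. Stretches with many members of a set were found in 250 kb tiles. Lists of genes were summarised by the median difference with a 95% order-statistic interval, the number of members past the size rule, and the percentile among 10000 random lists matched on mean expression, which describes these means only. The lists held naive and memory T cell genes, effector and cytotoxic genes, inhibitory receptors, exhaustion-associated transcription factors, NFAT and calcium response genes, AP-1 and bZIP factors, cell cycle genes, interferon-stimulated genes, glycolysis genes, chemokine receptors and homing genes, CD8 T cell identity genes, immediate early and dissociation stress genes, terminal effector against memory precursor genes, and markers of B cells, myeloid cells, NK and CD4 T cells, and erythroid cells and platelets.

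Alternatives were a pseudocount of 8, no minimum signal, quantile normalisation, centring of each column on its median, sets at 4-fold, a TPM pseudocount of 0.1 and a minimum of 1 TPM. Centring each chromosome in each column, and the alternatives for overlaps, were added after the data were seen. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, with fixed random seeds.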

Results

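The study followed mouse CD8+ T cells, the killer lymphocytes that respond to viral infection, from the resting naive state through an acute or a chronic response. Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 36 libraries of 15 groups. Gene expression was measured by RNA-seq in 8 libraries of 4 groups. Spleen cells of C57BL/6 mice gave naive cells (5 libraries from 4 replicates), labelled as uninfected. They also gave effector cells (3 libraries from 2 replicates) and memory cells (2 libraries) after infection with the lymphocytic choriomeningitis virus strain labelled LCMV Arm5, which the mouse clears. Exhausted cells (3 libraries) came from infection with LCMV Cl13, which persists. Among cells responding to Arm5, the day 8 populations SLEC (short-lived effector cells, 3 libraries) and MPEC (memory precursor effector cells, 3 libraries) were measured separately, as was 1 library of day 35 cells labelled KLRG1. The cultured cells (2 libraries per group) were P14 T cell receptor transgenic cells labelled 10U, 100U, 10U Iono, 10U PMAIono and 10U PMAIonoCsA, and C57BL/6 cells labelled Mock, NFAT CARIT and NFAT CARITDBDmut. The RNA-seq covered naive, effector, memory and exhausted cells, with 2 libraries each, and its naive cells carried the Arm5 label.

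The ATAC-seq table held 70532 regions on 20 chromosomes (mm9), with a median width of 583 bp, and 1 value per region and group: the authors' mean of scaled read counts per kb of region, called signal here. The RNA-seq table held the authors' mean TPM of 14492 genes per group. Because both tables held means without library values, no difference could be set against the spread between replicates, and no p-value or SD is given. A region was counted as different where the means lay at least 2-fold apart on the log2(signal + 1) scale and the higher mean reached 25, and a gene where log2(TPM + 1) means lay at least 2-fold apart and the higher reached 10 TPM. For the cultured groups the reads in regions could be worked out from the steps between low values, and came to 2.13 to 3.69 M per library, so that counting error alone amounted to an SD of 18.0% to 20.3% at a signal of 25 and 9.02% to 10.2% at 100. The day 35 KLRG1 library held 1.74 M reads in regions, with a counting SD of 33.5% at a signal of 25, and 8.98% of its regions stood at 0. The depth of the other in vivo columns is unknown, and of the intervals below, Poisson intervals cover counting error, those of shares and of list medians cover the number of regions or genes, and none covers the spread between replicates.

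Effector and SLEC chromatin were nearly the same, with a Spearman correlation across regions of 0.974 between their means. MPEC cells stood between SLEC cells (0.938) and memory cells (0.881), and memory cells were the in vivo group closest to naive cells (0.793). Exhausted cells were closest to effector cells (0.886) and least like naive cells (0.602) among the in vivo groups. NFAT CARIT cells stood apart from all others, with a highest correlation of 0.68, to Mock. The regions are not independent, so these values describe the means only. The first principal component held 38.5% of the variance and the second 14.6%. Few regions were steady: 3689 (5.23%) stayed within 2-fold across the 15 columns, and these were wide (median 947 bp), whereas 48509 (68.8%, median 565 bp) spanned at least 4-fold. Counting error adds to this span. The day 35 KLRG1 library was among the columns, and the 8.98% of regions at 0 there all count as spanning at least 4-fold. Wider regions hold more reads at the same signal, so counting error may also account for part of the difference in width. Of all regions, 19370 (27.5%) reached 25 in cultured cells but in no in vivo column, and 6483 (9.19%) did the reverse. These counts rest on the cut at 25 with no minimum fold, and they depend on scaling. Median signal was 24.7 to 33.9 in the cultured columns and 19.1 to 25.1 in the in vivo columns.

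**Figure D1:**
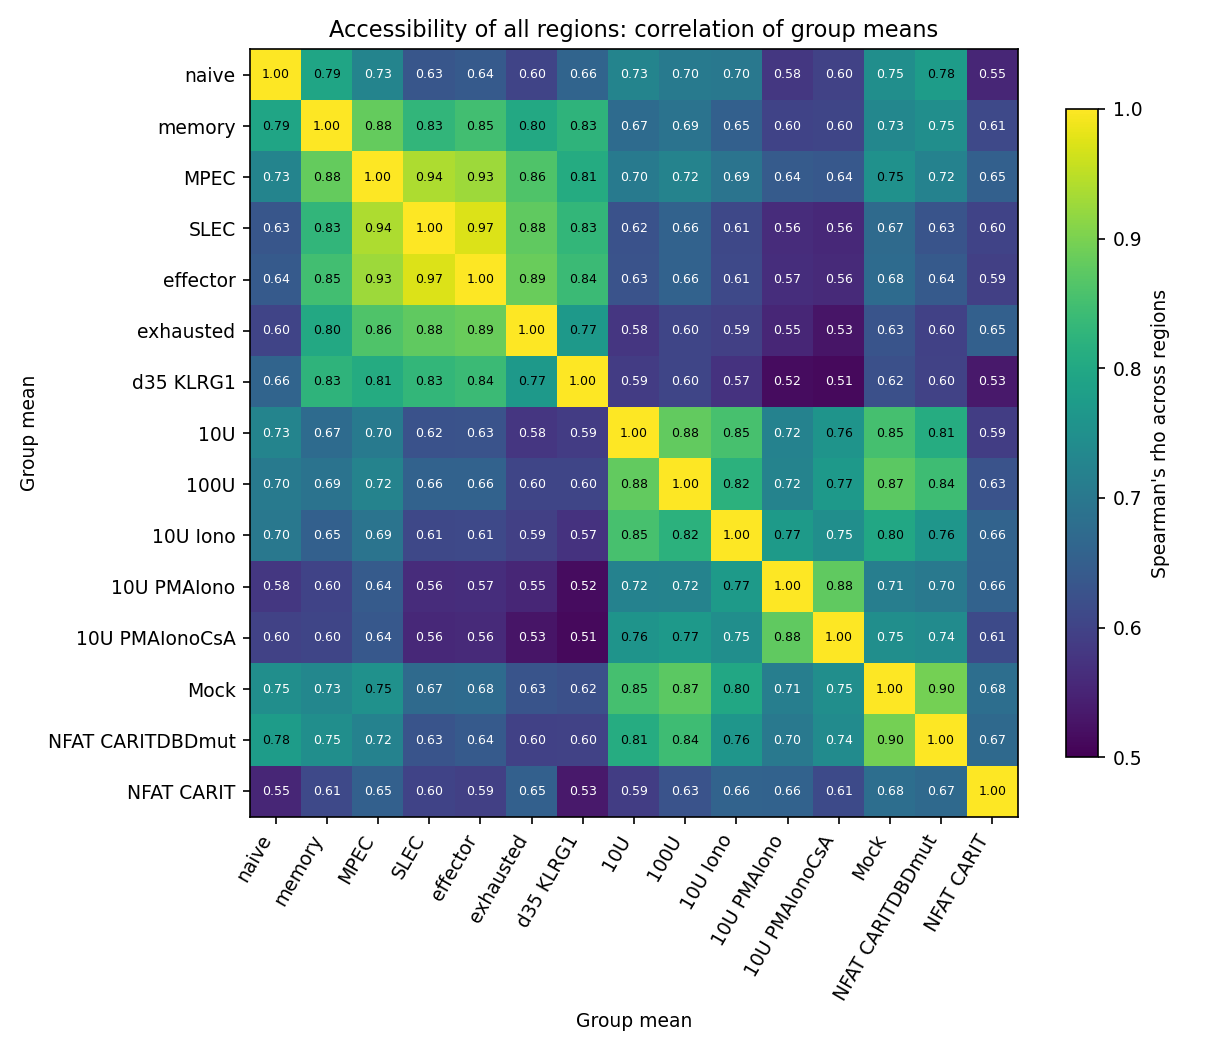
Spearman correlation across 70532 regions between the mean log2(signal + 1) of each pair of the 15 groups, with both axes listing the groups and the colour and number giving rho (no unit). Effector and SLEC cells share the highest value off the diagonal (0.974), and NFAT CARIT cells reach at most 0.68.

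Effector cells differed from naive cells in 19567 regions or 27.7% of those measured, of which 9004 were more accessible and 10563 less accessible in effector cells (46.0% higher, or 54.0% when columns were centred on their medians). At the region with the largest gain, chromosome 6 from 137530524 to 137531457, signal rose from 0.7 in naive to 295.5 in effector cells, and at the next, chromosome 17 from 83557322 to 83557898, from 0.1 to 185.0. The largest loss lay on chromosome 16 from 23174825 to 23175447, where signal was 134.0 in naive and 0.0 in effector cells, followed by chromosome 6 from 28300999 to 28301655 with 322.0 and 2.1. Gains also clustered: of 34 regions on chromosome 2 between 166271985 and 166499879, 25 were higher in effector cells, with mean signal 77.5 against 25.7. Chromosomes 11 and 19 stood higher as a whole in effector than in naive cells, by a median of 0.57 and 0.48 on the log2 scale, and held 1448 of the 9004 gains, or 791 gains once each chromosome was centred.

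The RNA of effector cells was marked by cytotoxic genes. All 20 effector and cytotoxic genes that reached 10 TPM were higher than in naive cells, with a list median of 5.58 on the log2 scale (95% order-statistic interval 3.14 to 7.90). Among them, the granzyme proteases that kill target cells went from 5.2 to 4943.0 TPM (Gzma), 4.9 to 3582.0 (Gzmb) and 0.9 to 1476.9 (Gzmk), and the chemokine Ccl5 from 59.3 to 14356.9. Klrg1, a receptor marking terminal effector cells, went from 0.4 to 852.6 TPM, the chemokine receptor Cx3cr1 from 0.4 to 603.0, and the transcription factor Tbx21 from 8.5 to 453.5. Naive and memory T cell genes went the other way, with 16 of 20 lower and a list median of -2.13 (-4.06 to -1.53): the lymph node homing receptor Ccr7 fell from 1793.9 to 19.9 TPM, the cytokine receptor Il7r from 365.5 to 21.0, and the transcription factors Tcf7 and Id3 from 645.4 to 84.8 and from 398.4 to 17.9. Of 19 cell cycle genes at 10 TPM, 18 were higher (median 3.75, interval 1.85 to 4.31), such as Ccnb2 (12.3 to 394.6 TPM) and Rrm2 (26.4 to 612.2). Inhibitory receptors were higher too, 7 of 10 (median 3.69, interval 0.18 to 5.84), with Pdcd1 at 188.9 against 4.4 TPM and Tigit at 355.9 against 1.7, while Btla was lower (14.6 against 32.6). In all, 733 genes were higher and 834 lower, against a median over all genes of -0.10.

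Other lists had smaller medians between effector and naive cells. The medians of the naive and memory, cytotoxic, cell cycle, inhibitory receptor, homing and terminal effector lists lay outside the range of 10000 random lists matched on expression, and those of the other lists lay inside it. The intervals of the homing list (-1.77 to 3.98) and the terminal effector list (-1.87 to 5.58) included 0. Interferon-stimulated genes had a median of 0.62 (3 of 15 higher), glycolysis genes 0.66 (5 of 14 higher), and chemokine receptors and homing genes 1.11, with 8 higher and 6 lower of 16. The list setting terminal effector genes beside memory precursor genes had a median of 1.93, with 10 higher and 7 lower of 19. CD8 T cell identity genes such as Cd8a (560.2 against 890.8 TPM) and Cd3e (723.2 against 907.2) had a median of -0.29, and none of 11 differed by 2-fold. NFAT and calcium response genes (median -0.13), AP-1 and bZIP factors (-0.24), exhaustion-associated transcription factors (0.44) and immediate early genes (-0.09) were nearer 0. Marker lists of other cell types had medians above 0, which many members near 0 TPM held down. The B cell list had a median of 0.47 (4 higher and 1 lower of 5 at 10 TPM), with the antigen presentation gene Cd74 at 80.2 against 15.1 TPM. The myeloid list had a median of 0.24, but all 3 members at 10 TPM were higher: Itgax (239.8 against 0.4), Cd68 (79.7 against 1.7) and Itgam (29.4 against 1.3). The NK and CD4 list had a median of 0.68 (2 of 3 higher). The erythroid and platelet list had a median of 1.46, with the platelet gene Pf4 at 10.7 against 1.4 TPM.

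**Figure D2:**
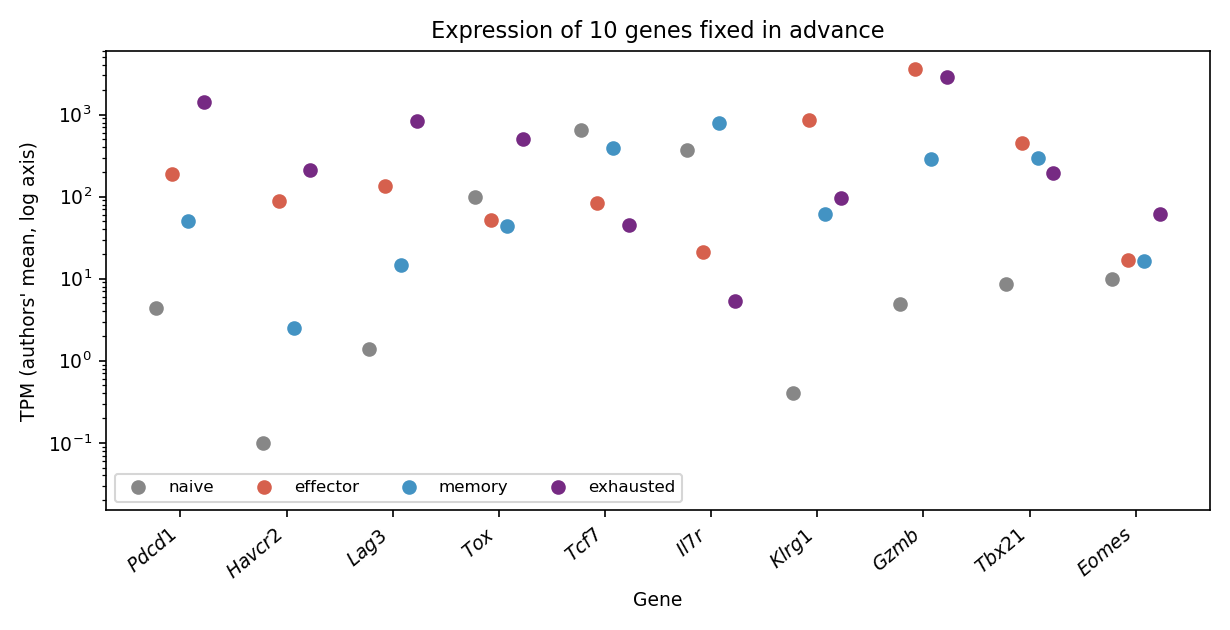
Expression of 10 genes fixed before the data were examined, as the authors' mean TPM (y axis, log scale) in naive, effector, memory and exhausted cells, 1 point per group mean with no error because only means were given. Pdcd1, Havcr2, Lag3 and Tox are highest in exhausted cells (1443.8, 213.6, 828.6 and 508.0 TPM), and Il7r is highest in memory cells (791.8 TPM).

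Memory cells kept a smaller difference from naive cells, with 4949 regions more and 5778 less accessible (46.1% higher, but 52.5% with columns centred on their medians and 54.1% without the minimum signal). The largest gain lay on chromosome 7 from 58979277 to 58979863 (524.2 in memory, 3.6 in naive cells) and the largest loss on chromosome X from 163842625 to 163843154 (0.7 and 61.0). In RNA, 399 genes were higher and 264 lower. All 20 measured cytotoxic genes at 10 TPM were again higher than in naive cells (median 4.56, interval 2.39 to 5.72), including Ccl5 (18392.4 against 59.3 TPM), the activating receptor Klrk1 (425.0 against 0.6), Gzmk (455.2 against 0.9) and Fasl (132.3 against 0.4), while the cell cycle list stood at -0.20 with 1 of 12 lower and none higher. The naive and memory list was mixed, with 2 higher and 7 lower of 20 (median -0.76): Il7r was at 791.8 TPM against 365.5 and Cd28, a costimulatory receptor, at 235.4 against 92.2, whereas Ccr7 was at 238.8 against 1793.9. Among homing genes, the integrin Itgae was at 5.7 against 196.8 TPM and Ccr9, a gut homing receptor, at 4.0 against 160.3. Some markers of other cell types rose as well: the B cell list had a median of 0.81, above all random lists (at most 0.65), with the antigen presentation genes H2-Aa at 62.0 against 4.0 TPM and Cd74 at 97.6 against 15.1, and the NK receptor Klrb1c was at 211.0 against 1.3.

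To ask what separates memory from effector cells, the same measures were compared directly. Memory cells were more accessible at 5172 regions and less accessible at 5754, so that 47.3% were higher, but the direction turned with each chromosome centred (4922 higher, 4231 lower, 53.8% higher) and without the minimum signal (59.0%). On chromosome 4 from 10680237 to 10680838 signal was 67.4 in memory and 1.3 in effector cells, and on chromosome 9 from 73024255 to 73024998 it was 0.5 and 55.1. A stretch of chromosome 7 from 65756081 to 65999754 held 21 higher regions among 38, with mean signal 76.1 in memory, 31.6 in effector and 83.1 in naive cells. Losses were uneven across the genome: 1816 of the 5754 (31.6%) lay on chromosomes 11 and 19, which hold 9.25% of regions, and 375 were left there after each chromosome was centred on its own median.

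**Figure D3:**
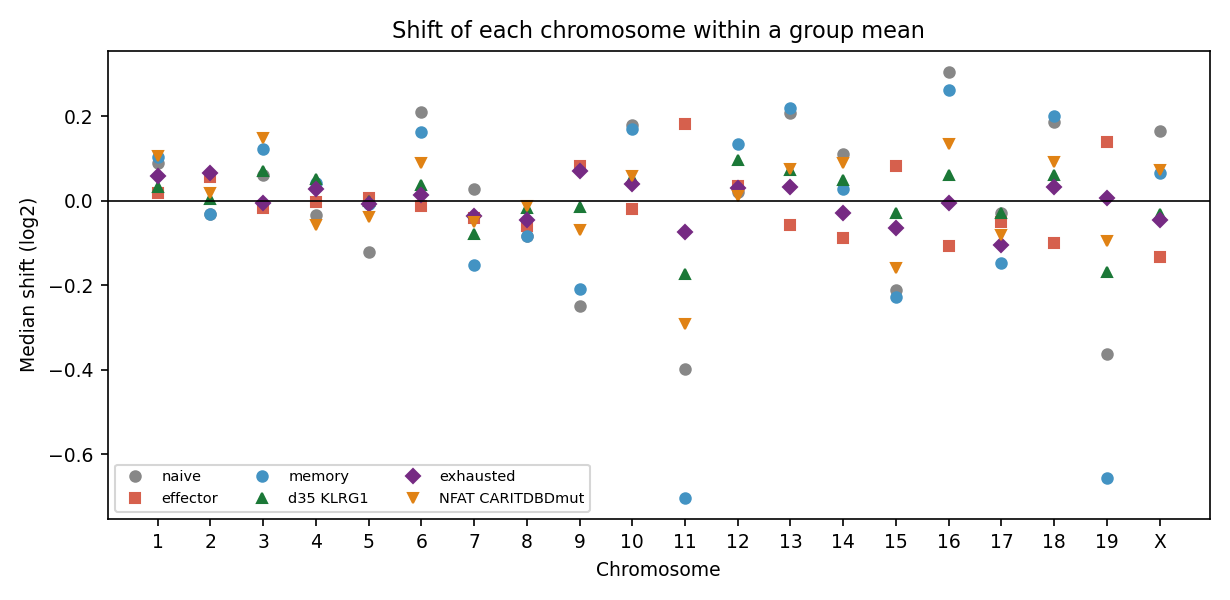
Median shift of each chromosome (x axis) in the mean of 6 groups, as the median log2 difference of its regions from their mean over the 15 groups, less that of all chromosomes (y axis, log2 units), over regions at 25 or more in every group; 1 point per group mean, with no error. Chromosomes 11 and 19 lie lowest in memory cells (-0.70 and -0.66) and naive cells (-0.40 and -0.36), and above 0 in effector cells (0.18 and 0.14).

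Proliferation genes were lower in the RNA of memory than effector cells. Of 19 cell cycle genes at 10 TPM, 18 were lower (median -3.98, interval -4.63 to -1.99), such as Ccnb2 at 7.5 against 394.6 TPM and Ube2c, which targets mitotic proteins for destruction, at 8.2 against 373.2. Naive and memory genes were higher, 10 of 18 (median 1.27, interval 0.80 to 2.28): Il7r 791.8 against 21.0, Ccr7 238.8 against 19.9 and Tcf7 389.2 against 84.8 TPM. Of 21 cytotoxic genes 8 were lower and 1 higher (median -0.49), with Gzma at 109.4 against 4943.0 and Klrg1 at 61.2 against 852.6 TPM, but Ccl5 at 18392.4 against 14356.9. Interferon-stimulated genes had a median of -0.81 (6 of 15 lower), glycolysis genes -0.49 (1 of 14 lower) and inhibitory receptors -0.94 (4 lower, 2 higher of 10). AP-1 factors (3 of 8 higher) and immediate early genes (6 of 11 higher), lists that share members, both had medians of 0.55, inside the range of random lists, with Fos at 31.0 against 8.3, Jun at 56.1 against 8.9 and Junb at 899.4 against 244.1 TPM. Chemokine receptor and homing genes (0.25) and the terminal effector and memory precursor list (0.27) had 4 higher and 1 lower of 14, and 6 higher and 6 lower of 19. Markers of other cell types moved too, Klrb1c to 211.0 from 66.2 TPM, Itgam to 1.8 from 29.4, Itgax to 78.9 from 239.8 and Cd68 to 28.5 from 79.7, with 1 higher and 3 lower of 4 myeloid markers. Over all genes 474 were higher and 391 lower.

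Exhausted cells differed from naive cells in 19409 regions, 8174 more and 11235 less accessible, and the 2 directions split as 42.1% higher, or 53.5% higher when each column was centred on its median. The largest gain was on chromosome 3 from 157466150 to 157466735, with signal 379.8 in exhausted and 0.0 in naive cells. The largest loss was on chromosome 5 from 72294576 to 72295108, with 1.2 and 227.1. The expression gap was also wide, with 1390 genes higher and 1240 lower than in naive cells, though 116 of the lower genes are listed at 0 in exhausted cells (against 6 of those lower in effector than naive cells), among them housekeeping genes such as Uros and Ercc2. Cytotoxic genes (18 of 19 higher, median 4.29), inhibitory receptors (11 of 12 higher, median 5.71) and cell cycle genes (20 of 20 higher, median 4.21) stood above naive cells, and naive and memory genes stood below (15 of 20 lower, median -3.02), with Ccr7 at 10.1 against 1793.9 TPM. The myeloid gene Lyz2 was at 100.8 against 0.5 TPM and the platelet gene Pf4 at 31.7 against 1.4.

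Changes from naive cells overlapped between effector and exhausted cells. Of the regions more accessible in effector cells, 4999 (55.5%) were also more accessible in exhausted cells, where independent lists would share 1043, and of those less accessible 8757 (82.9%) were shared, where independent lists would share 1683. Between effector and memory cells, 3413 gains (37.9% of effector gains; 632 for independent lists) and 5077 losses (48.1%; 865 for independent lists) were shared. Groups simulated without any change but with the same naive values shared 6.45 to 10.7 regions on average per direction and at most 20. Both comparisons used the same naive mean and it could not be split, so part of the excess may come from the shared naive libraries. A loss could be counted only where naive signal reached 25, and the median naive signal over all regions was 25.1. The figures for independent lists counted every region as able to show a loss, so 1683 and 865 are too low as baselines for losses.

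Exhausted and effector cells, from chronic and acute infection, differed in 3221 regions more accessible and 4237 less accessible in exhausted cells. On chromosome 7 from 120061485 to 120062323 signal was 97.3 in exhausted and 0.4 in effector cells, and on chromosome 8 from 124499084 to 124499624 it was 98.2 and 0.8. The largest loss, on chromosome 6 from 82884736 to 82885369, had 6.5 and 170.9. Taking regions higher in exhausted than in both effector and memory cells gave a set of 2232, and a stretch of chromosome 16 from 84379999 to 84497990 belonged to it entirely: all 11 of its regions were higher, with mean signal 96.2 in exhausted, 12.2 in effector, 9.78 in memory and 2.49 in naive cells. The set lower in exhausted than in both others held 1828 regions.

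Inhibitory receptors were the list that most set exhausted from effector RNA, with 10 of 12 higher and none lower (median 1.98, interval 1.26 to 2.93). Pdcd1, which encodes PD-1, was at 1443.8 against 188.9 TPM, Lag3 at 828.6 against 136.1, Tigit at 1090.0 against 355.9, Havcr2 at 213.6 against 88.3, Cd244 at 116.0 against 3.9 and Ctla4 at 111.4 against 21.6. Of 10 exhaustion-associated transcription factors 7 were higher (median 1.41, interval 0.59 to 3.26), including Tox (508.0 against 52.3 TPM), Tox2 (166.8 against 2.8), Nr4a2 (109.4 against 2.6), Eomes (61.4 against 17.0) and Batf (460.4 against 209.7). The NFAT and calcium response list had a median of 0.50 (interval -0.14 to 1.57, 5 of 12 higher), inside the range of 10000 matched random lists (at most 0.81), or 0.87 with genes under 1 TPM left out, with the costimulatory receptor Tnfrsf9 at 291.5 against 46.0 TPM and Egr1 at 37.6 against 7.6. Chemokines that attract T cells and monocytes were higher, Ccl3 at 574.1 against 35.4 and Ccl4 at 1247.2 against 167.1 TPM, while Klrg1 (95.6 against 852.6), the chemokine receptor Ccr2 (19.8 against 301.8) and Klrk1 (23.3 against 253.1) were lower. The genes with the largest rises outside the lists were Gm4956 (106.1 against 0.2 TPM), the receptors Glp1r (48.6 against 0.4) and Gpr56 (211.7 against 6.1), and Penk (31.2, listed at 0 in effector cells). In all, 872 genes were higher and 548 lower (53 of these listed at 0 in exhausted cells), against a median over all genes of 0.13, which was not subtracted from the list medians.

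Of the remaining lists between exhausted and effector cells, homing, naive and memory, and terminal effector and memory precursor genes had medians below those of all 10000 matched random lists, and the other medians lay inside the random range. For the naive and memory list (lowest random median -0.643) and the terminal effector and memory precursor list (-0.649) the margin was small. Their intervals, -1.05 to 0.872 and -1.3 to 0.585, included 0, while that of homing genes was -1.67 to -0.248. Cytotoxic genes had 4 higher and 8 lower of 20 (median -0.41), naive and memory genes 3 higher and 6 lower of 17 (median -0.68), and homing genes 3 higher and 6 lower of 14 (median -0.81). Cell cycle genes were near effector levels, with 1 of 20 higher (median 0.43). Interferon-stimulated genes (0.35), glycolysis genes (-0.38), AP-1 factors (0.13), immediate early genes (0.49) and the terminal effector and memory precursor list (-0.68) had 3, 0, 4, 6 and 3 members higher and 1, 1, 1, 0 and 7 lower. CD8 identity genes had a median of 0.02. Markers of other cell types went both ways. In exhausted cells the myeloid gene Lyz2 was at 100.8 against 3.2 TPM, the macrophage gene C1qa at 12.1 against 0.3, and the platelet genes Pf4 and Ppbp at 31.7 against 10.7 and 35 against 5.8, whereas Itgax (31.5 against 239.8), Itgam (3.5 against 29.4) and the NK receptor Klrb1c (4.8 against 66.2) were lower. The list medians were 0.63 for erythroid and platelet markers, 0.19 for B cell markers, -0.14 for myeloid markers and -0.54 for NK and CD4 markers. The exhausted column also listed 4191 genes at 0, against 1951 to 2150 in the other 3, and 80 genes at 0 there had at least 5 TPM in each other group (3 such genes for naive cells, 0 for effector and memory cells). For genes at 0 in exhausted cells, such as Tnfrsf25 (48.6 TPM in effector cells), the sterol synthesis gene Sqle (45.0) and Ifitm1 (44.0), only the listing at 0 is given, with no fold.

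Compared with memory cells, exhausted cells were more accessible at 5396 regions and less accessible at 6644, with 44.8% higher, or 56.3% when columns were centred on their medians. Signal on chromosome 10 from 93971497 to 93972079 was 246.1 in exhausted and 1.6 in memory cells, and on chromosome 8 from 117412171 to 117412808 it was 2.5 and 169.4. Expression differed at 1173 genes higher and 999 lower, of which 80 are listed at 0 in exhausted cells. Inhibitory receptors had 9 of 12 higher (median 3.04), exhaustion-associated factors 9 of 10 (1.97) and cell cycle genes 20 of 20 (4.36), and naive and memory genes had 13 of 18 lower (-2.15), with Il7r at 5.3 against 791.8 TPM. Gzma was at 3450.3 against 109.4 TPM, the signalling gene Rgs16 at 74.9 and listed at 0 in memory cells, and Jun, an AP-1 subunit, at 1.5 against 56.1. Of 4 myeloid markers at 10 TPM 3 were higher and 1 lower: Lyz2 was at 100.8 against 10.9 TPM and C1qa at 12.1 against 0.2, but Itgax at 31.5 against 78.9. The NK receptor Klrb1c was lower, at 4.8 against 211.0 TPM.

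SLEC and MPEC cells, both from day 8 of the acute response, differed in fewer regions than the in vivo pairs above, with 1422 regions higher in SLEC and 1540 higher in MPEC cells. The share higher in SLEC was 48.0%, or 58.4% when columns were centred on their medians. On chromosome 18 from 80732282 to 80733294 signal was 78.1 in SLEC and 3.8 in MPEC cells, and on chromosome 11 from 121471509 to 121472099 it was 204.9 and 13.6. That chromosome 11 region was also among the largest losses from effector (168.0) to memory cells (4.2), with a log2 difference of -5.02, or -4.14 after its chromosome was centred. The largest MPEC-side difference was on chromosome 3 from 38178965 to 38179545, with 3.4 in SLEC and 62.9 in MPEC cells. Regions that set the day 8 populations apart also differed between memory and effector cells, whose column is close to that of SLEC cells: of the SLEC-higher regions 65.7% (exact binomial interval 63.1% to 68.2%) were less accessible in memory than effector cells, against at most 13.8% in 10000 random sets of the same level, and of the MPEC-higher regions 52.7% (50.2% to 55.2%) were more accessible, against at most 13.6%. From naive to effector cells, 86.0% of SLEC-higher regions gained and 58.2% of MPEC-higher regions lost accessibility.

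Day 35 KLRG1 cells, measured in 1 library, were about as close to effector cells (Spearman 0.841 across regions) as to SLEC (0.832) and memory cells (0.826), and farther from naive cells (0.662). Against memory cells, 4604 regions were higher and 4620 lower, or 8696 and 14367 without the minimum signal, and no replicate check was possible. Regions higher in SLEC than MPEC cells were higher in day 35 KLRG1 than memory cells in 29.2% of cases (26.8% to 31.6%; random sets at most 10.2%), and MPEC-higher regions were lower in 48.3% (45.8% to 50.8%; random sets at most 10.3%). The region on chromosome 11 from 75678062 to 75678618 had a signal of 50.0 (95% Poisson interval 29.1 to 80.1) in day 35 KLRG1 cells and 0.0 in memory cells.

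**Figure D4:**
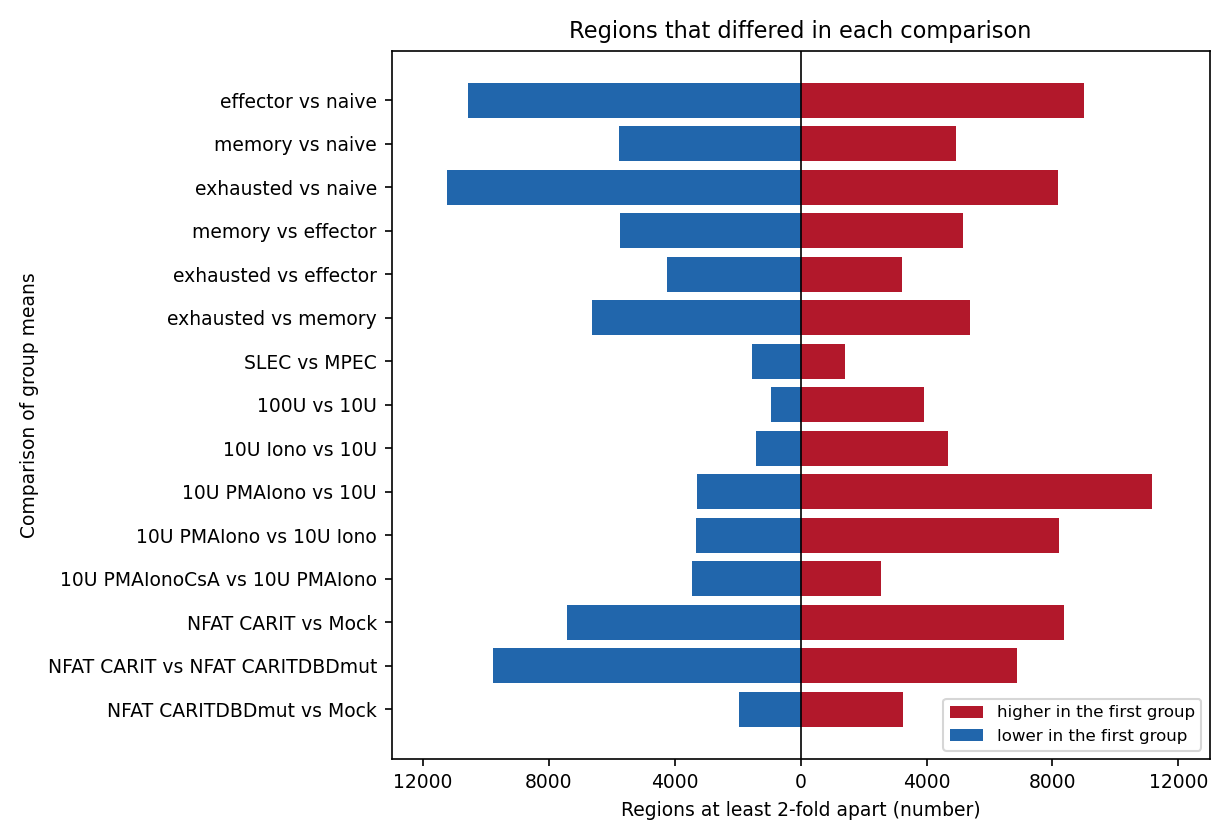
Number of regions at least 2-fold apart (x axis) in each of 15 comparisons of group means (y axis), with regions higher in the first group drawn to the right and those lower to the left; no error bars, since only means were given. Exhausted against naive cells has the most losses in vivo (11235), and 10U PMAIono against 10U has the most gains in culture (11154).

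The cultures were then compared with each other, first by dose and added stimulus and then by construct. Cells labelled 100U and 10U, which differ in the dose of an agent that the labels do not name, differed in 3930 regions higher and 937 lower at 100U. The largest gain, on chromosome 6 from 142403970 to 142404604, went from 6.7 (95% Poisson interval 2.89 to 13.2) to 64.5 (50.1 to 81.8). The largest loss, on chromosome 9 from 84998802 to 84999393, went from 50.2 (37.9 to 65.2) to 8.2 (3.55 to 16.1). Counting error alone gave 165 regions higher and 171 lower on average over 20 redraws. The share higher was 80.7% as deposited, but 58.2% after quantile normalisation and 51.3% with columns centred on their medians, so the excess of gains depended on the scaling.

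Iono, read here as the calcium ionophore ionomycin, raised accessibility at 4678 regions and lowered it at 1417 relative to 10U. Signal on chromosome 13 from 5405243 to 5405754 was 99.8 (81.6 to 121) with Iono and 0.0 (to 3.83) without, and on chromosome 6 from 22341009 to 22341508 it was 64.5 (49.9 to 82.1) and 0.0 (to 3.92). Losses were shallower, the largest going from 52.9 (40.2 to 68.4) to 9.8 (5 to 17.3) on chromosome 7 from 85619767 to 85620347. The share higher was 76.8%, 60.8% after quantile normalisation and 57.0% after median centring, and counting error alone gave 109 higher and 112 lower.

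PMA, a phorbol ester that activates protein kinase C, was combined with Iono. With PMAIono 11154 regions were higher and 3278 lower than in 10U, the largest gain being on chromosome 1 from 166860502 to 166861001, from 1.1 (0.031 to 5.99) to 290.8 (258 to 327), and the largest loss on chromosome 11 from 98813999 to 98814568, from 56.6 (43.3 to 72.7) to 4.9 (1.68 to 11.1). Against Iono alone, PMAIono had 8223 regions higher and 3340 lower. The largest loss against Iono was on chromosome 7 from 81604244 to 81604743, where signal was 87.0 (69.9 to 107) with Iono and 0.0 (to 3.80) with PMAIono. The share higher was 77.3% against 10U (57.9% after quantile normalisation, 51.5% after median centring) and 71.1% against Iono (56.9% and 60%). Counting error alone gave 107 to 131 regions per direction.

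CsA, read here as cyclosporin A, an inhibitor of the calcineurin phosphatase that activates NFAT, took away part of the PMAIono response. With CsA 3453 regions were lower and 2550 higher than with PMAIono alone. Several sites went to 0: chromosome 12 from 15938830 to 15939343 fell from 89.2 (71.6 to 110) to 0.0 (to 4.10), and chromosome 18 from 42081620 to 42082281 from 75.7 (61.4 to 92.3) to 0.0 (to 3.18). A gain lay on chromosome 14 from 37315732 to 37316257, from 2.8 (0.548 to 8.37) to 65.7 (50.2 to 84.5). Of the 11154 regions gained with PMAIono, 2633 (23.6%) were at least 2-fold lower with CsA, where counting error alone gave 0.405% on average and at most 0.517%, and 58.9% were still at least 2-fold above 10U. The PMAIono mean was used both to choose these regions and to compare them with CsA, so part of the share may come from spread between its libraries.

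NFAT CARIT, an engineered NFAT known from earlier work as constitutively active and altered so that it does not pair with AP-1, changed the chromatin of cultured cells broadly. Against Mock 8371 regions were higher and 7413 lower (53.0% higher, but 49.7% after quantile normalisation, 47.7% after median centring and 46.0% without the minimum signal). Sites opened from no detectable signal: chromosome 4 from 144873207 to 144873817 had 158.9 (137 to 184) with NFAT CARIT and 0.0 (to 3.53) in Mock, and chromosome 9 from 119921819 to 119922318 had 120.3 (99.0 to 145) and 0.0 (to 4.31). The largest loss, on chromosome 16 from 94067904 to 94068533, went from 119.6 (99.8 to 142) to 0.7 (0.00874 to 4.49). Counting error alone gave 162 higher and 160 lower.

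NFAT CARITDBDmut, whose name points to a mutated DNA-binding domain, changed far less. NFAT CARIT and its mutant differed in 6888 regions higher and 9784 lower with the intact protein, whereas the mutant and Mock differed in 3237 higher and 1972 lower. On chromosome 10 from 94656660 to 94657159 signal was 166.6 (141 to 195) with NFAT CARIT and 0.0 (to 3.50) with the mutant, and on chromosome 2 from 131480459 to 131481010 it was 0.0 (to 3.60) and 90.1 (73.7 to 109). The largest gains of the mutant over Mock all lay on chromosome 2 near 168329805 to 168397288, led by 219.1 (200 to 240) against 7.3 (3.87 to 12.5), and were shared with NFAT CARIT (206.5). Whether the reads there came from opened chromatin or from the introduced construct's own DNA was not settled, as described at the end. Chromosomes 11 and 19 held 510 of the 1972 losses, or 182 after each chromosome was centred. The split between mutant and Mock depended on scaling, with 62.1% higher as deposited, 46.2% after quantile normalisation and 36.1% after median centring, and counting error alone gave 132 higher and 123 lower.

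Regions that set exhausted cells apart were then followed in the cultures, to see whether they also differed with NFAT CARIT. Binding was not measured and no engineered NFAT able to pair with AP-1 was included, so the part of AP-1 was not tested. Of the 2232 regions higher in exhausted than in effector and memory cells, 791 (35.4%, exact binomial interval 33.5% to 37.5%) were higher with NFAT CARIT than in Mock, against 11.9% of all regions and at most 12.5% in 10000 random sets matched on level. Against the mutant the share was 32.8% (30.9% to 34.8%; random sets at most 10.6%), and for the mutant against Mock it was 3.05% (2.37% to 3.85%), within the random range (median 3.36%). Mean signal over the set was 69.8 in exhausted and 18.0 in effector cells, and 47.6 with NFAT CARIT, 23.2 with the mutant and 21.0 in Mock. Iono raised 13.0% of the set (random sets at most 6.23%) and PMAIono 24.2% (at most 14.5%), CsA lowered 9.09% relative to PMAIono (at most 5.11%), and 100U raised 4.61%, within the random range. Of the 1828 regions lower in exhausted cells, 34.5% were lower with NFAT CARIT than in Mock (random sets at most 12.5%) and 44.2% lower than with the mutant (at most 15.8%).

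Loss of accessibility with NFAT CARIT was shared by some other sets. Relative to Mock, NFAT CARIT was lower at 20.5% of regions lower in effector than naive cells, 21.3% of regions higher in memory than effector cells and 33.1% of regions higher in MPEC than SLEC cells (random sets at most 10.4%, 11.7% and 11.9%). For the opposite sets, higher in effector than naive, lower in memory than effector and higher in SLEC than MPEC cells, the shares were 9.98%, 8.43% and 11.5%, inside the random range. Relative to the mutant the first 3 shares were 31.1%, 30.6% and 41.4%, but the mutant itself was higher than Mock at 8.56%, 7.56% and 5.78% of these regions, above random sets (at most 4.98%, 5.32% and 5.19%). Gains with NFAT CARIT against Mock reached 14.1% for regions higher in effector than naive cells (random sets at most 12.2%). Starting from the construct, 5399 regions were higher with NFAT CARIT than in both Mock and mutant. Of these, 14.5% were higher in exhausted than effector cells (random sets at most 4.17%, all regions 4.57%), 20.8% were higher with Iono than 10U (at most 5.22%), 37.9% with PMAIono than 10U (at most 13.8%) and 15.8% lower with CsA than PMAIono alone (at most 4.65%). A share of 14.9% was also higher in effector than naive cells (random sets at most 8.39%, all regions 12.8%). The NFAT CARIT column is shared by the comparisons with Mock and with the mutant, so these are not independent of each other.

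**Figure D5:**
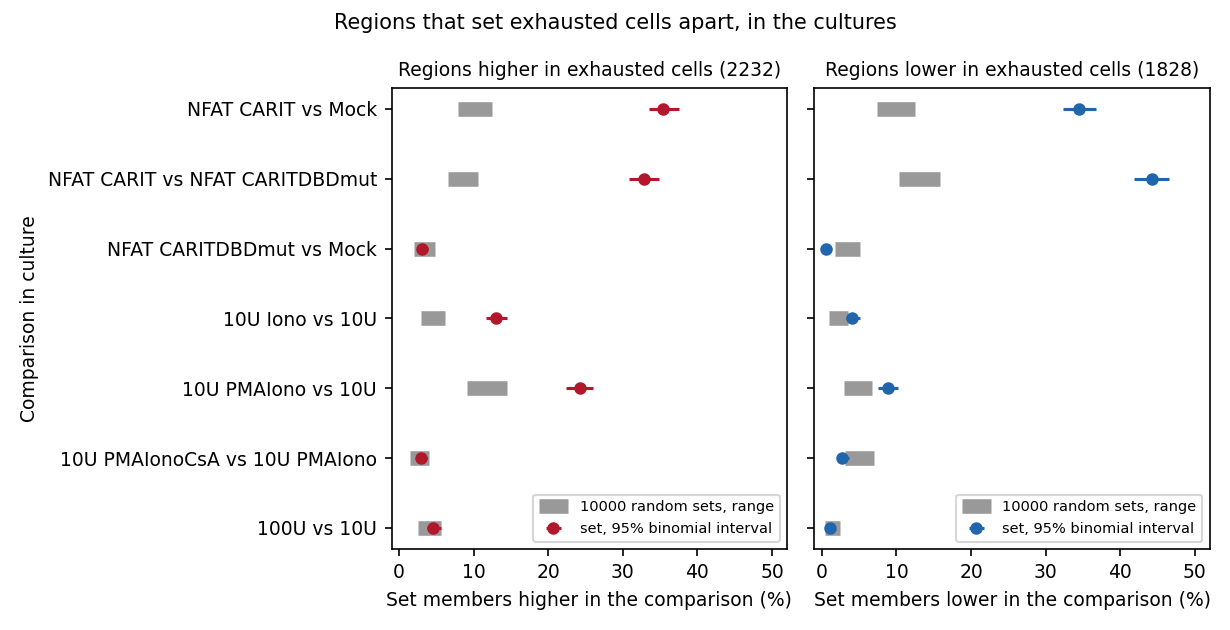
Share of the 2232 regions higher (left, %) and the 1828 regions lower (right, %) in exhausted than in effector and memory cells that were at least 2-fold higher or lower in each comparison in culture (y axis); points are shares with exact 95% binomial intervals and grey bars the range of 10000 random sets matched on level. For NFAT CARIT against Mock the share is 35.4% on the left, above the random range that ends at 12.5%, and for the mutant against Mock it is 3.05%, inside it.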

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

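The tests with each chromosome centred, and the overlaps under other settings, were chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because the tables give 1 mean per group and carry no replicate numbers. For the same reason leaving out each replicate, the replicate block, fits of only the compared groups, technical replicates as separate libraries, tests without a fold minimum, a split of the naive libraries, edgeR and DESeq2 on recovered reads, and camera with an estimated correlation were not run, and the mean over a gene's regions was not formed because regions were not assigned to genes. Nothing below therefore speaks to replicate error. Among columns whose depth could be worked out, the day 35 KLRG1 library had the fewest reads (1.74 M), and at 2-fold the size rule found 44.5% of simulated changes between NFAT CARIT and Mock.

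Counts of changed regions stayed within 1.5 times in all 15 comparisons under quantile normalisation, median centring and chromosome centring, in 10 of 15 with a pseudocount of 8 and in 4 of 15 with no minimum signal. The share of higher regions among them depended more on scaling: it moved by over 10 points in 5 comparisons under quantile normalisation in 8 under median centring, in 5 without the minimum, and in 0 with chromosomes centred. Without the minimum, which lets in regions with few reads by construction, the counts were 29693 for effector and 20351 for memory against naive cells, 29144 for exhausted against naive, 21538 for memory and 13765 for exhausted against effector, 22483 for exhausted against memory, 7718 for SLEC against MPEC, 10394 for 100U and 11451 for 10U Iono against 10U, 11059 for CsA against PMAIono alone, and 10203 for the NFAT mutant against Mock. In memory against effector cells 59.0% were then higher (47.3% with the minimum), in SLEC against MPEC cells 26.8% (48.0%), in PMAIono against 10U 66.4% (77.3%) and against Iono 59.9% (71.1%), and in the NFAT mutant against Mock 51.1% (62.1%). With a pseudocount of 8, which shrinks differences of low values by construction, they were 1915 for SLEC against MPEC, 2409 for 100U and 3855 for 10U Iono against 10U, 3788 for CsA against PMAIono alone and 2729 for the NFAT mutant against Mock.

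The sets that tie exhausted cells to NFAT CARIT kept their direction at 4-fold: the share of exhausted-higher regions was 38.0% against Mock, 37.3% against the mutant and 1.56% for mutant against Mock, and that of exhausted-lower regions 47.7% against Mock and 53.6% against the mutant; the cause of these moves was not tested. Overlaps of effector and exhausted changes were 4303 gains and 7370 losses with a pseudocount of 8, and 4805 and 8561 with chromosomes centred. Of 51 medians of gene lists, all stayed within their intervals with a 1 TPM minimum, and with a pseudocount of 0.1 the erythroid and platelet list, with 5 measured genes near 0, alone moved, to 2.32 from 1.46 between effector and naive cells; the cause was not tested. The intervals are wide, however, and medians moved by over 1.5 times without changing sign in several lists with many genes near 0 TPM. With a 1 TPM minimum, those between exhausted and effector cells were 0.87 for NFAT genes (0.50 with all genes), 0.66 for interferon-stimulated genes (0.35), 0.49 for AP-1 factors (0.13) and 0.85 for immediate early genes (0.49), the last list also giving 0.97 (0.55) between memory and effector cells. Between effector and naive cells they were 0.71 for exhaustion-associated factors (0.44), 1.52 for B cell markers (0.47) and 1.49 for myeloid markers (0.24). Random lists were not drawn again for these.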

Other observations

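Tests chosen only after the result was seen were those of equal region density, of cell number, of matched level, of the vector, and all 3 on the chromosome 2 stretch; those of sparse DNA, RNA output and chromosome-wide shifts were written before their results.

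Ribosomal protein genes, which build the translation machinery, took less of the RNA in activated cells. Their summed expression was 165100 TPM in naive, 108200 in memory, 63330 in effector and 49940 in exhausted cells. The 76 of these genes that reached 10 TPM in some group were then compared singly. In effector cells 62 of the 76 were at least 2-fold lower than in naive cells (median log2 difference -1.38), in exhausted cells 69 (-1.71), and in memory cells 7 (-0.65). From effector to memory cells 13 were higher (median 0.72). TPM are shares of a fixed total, so a lower share of these genes raises the TPM of all others.

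Some chemokine receptor and adhesion genes stood above naive cells in all 3 other states, with effector and memory cells within 2-fold of each other. Cxcr6, a receptor of tissue-resident cells, was at 505.9 TPM in naive, 2177.7 in effector, 2707.5 in memory and 1455.8 in exhausted cells, and Cxcr3 at 69.6, 712.0, 1061.3 and 599.3. The adhesion receptor Itgb1 was at 37.4, 604.1, 728.1 and 189.7 TPM. Ly6c2, a surface marker of activated CD8 cells, was at 1103.8, 6502.5, 5471.1 and 960.6, so not above naive in exhausted cells. The dual-specificity phosphatase Dusp1 was highest in exhausted cells (317.3 TPM against 30.4 in effector and 95.1 in memory cells). The costimulatory receptor Cd27 stayed between 318.0 and 583.0 TPM in the 4 states. These genes were chosen after their values were seen.

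Whole chromosomes shifted between memory and effector cells. Chromosome 11 was lower by a median log2 of -0.89 and chromosome 19 by -0.80, and 31.6% of regions lost in memory cells lay there. Cell number does not account for the shift alone, because naive cells, all from 50000-cell libraries, stood at -0.398 on chromosome 11 and day 35 KLRG1 cells, from 10000 cells, at only -0.172, although 1 of the memory libraries used 10000 cells and a part in memory cells (-0.702) stays open. Region density was weighed in 1 Mb tiles: in sparse tiles of both chromosomes the difference was -0.638 (bootstrap interval -0.895 to -0.174, 35 tiles), which cannot be told apart from a density trend within the bounds set (a first version with a normal-approximation interval fell just past them), but against tiles elsewhere of equal density it was -0.917 (interval ending at -0.831, 145 tiles), which argues against density alone. Both intervals treat tiles of the same chromosome as independent, so they are likely too narrow for a shift of whole chromosomes. On other chromosomes the median difference was 0.473 in sparse tiles (640 tiles) and 0.103 in dense tiles. On chromosomes 11 and 19 it was -0.638 and -0.855, lower at either density, which also argues against density alone. Lower RNA output did not accompany the shift, since genes of these chromosomes differed from other genes by a median log2 of 0.00523 (-0.0380 to 0.0495). A chromosome-wide technical source such as GC content, untested without a genome, may underlie a part of the losses on chromosomes 11 and 19. The RNA medians cannot tell such a source from a real change of accessibility, because RNA need not follow it.

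Regions higher in exhausted cells were often higher with NFAT CARIT. The level of the regions does not account for this, as the share was 35.4% against at most 12.5% in matched sets, nor do chromosome-wide shifts, as the share stayed 3.1 times that of all regions (36.4% against 11.7%) with each chromosome centred. The vector does not either, as the mutant raised 3.05% of them (2.37% to 3.85%). A candidate explanation is that NFAT bound without AP-1 opens a part of the sites that mark exhaustion. It stays a hypothesis, because binding was not measured, motifs were not searched and no group held an engineered NFAT able to pair with AP-1. GC content and the spread between libraries are also untested. Losses with NFAT CARIT against Mock were not particular to exhausted-lower regions (34.5%), being above random sets in 3 of 6 other sets (20.5% to 33.1%) and not in the other 3 (8.43% to 11.5%).

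A 67.5 kb stretch of chromosome 2, from 168329805 to 168397288, held 5 of the 11 regions genome-wide that were at least 2-fold higher with both NFAT constructs than in every other column (29.5 to 219.1 against at most 16.4, a gap these regions were picked for). The tables do not settle the cause. Opening of the whole stretch cannot be told apart, as its 14 regions had a median log2 difference between mutant and Mock of 0.573, and nor can binding of NFAT, since the median log2 difference of 0.142 between mutant and NFAT CARIT comes from regions chosen for being high with both. The median of 0.573 includes the 5 picked regions. The other 9, left out by that choice, had a median of -0.191 (range -0.774 to 1.62). Reads from the introduced construct's own DNA, aligned to the gene it was copied from, may be the source, but the log2 difference between constructs, which spread over 0.792 across the 5 regions and within 95% of redraws at 1 common ratio (0.969), spread over only 0.366 in the 6 regions elsewhere chosen in the same way. Nfatc2, the gene of NFAT1, lies on chromosome 2 in GRCm38.p6, but its place in mm9 was not checked here.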
